A study of Rattus norvegicus with 12 samples.

How the data were processed

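Total RNA from 12 samples of primary rat cardiomyocytes, 3 each for control and for SIN-1 treatment of 70 min, 4 h and 8 h, was amplified and biotin-labelled with a whole-transcript kit and hybridised to one-colour arrays, per the labels' protocols. The authors summarised the arrays with RMA in Affymetrix Expression Console 1.3.1.187, per the submitters' processing notes, and deposited 1 table of 36685 probes by 12 arrays. The deposited values were taken as log2 expression: no unit is stated, and the scale was inferred from the values, which ran from 1.19 to 13.63 with similar distributions in all arrays. RMA corrects background, normalizes quantiles between arrays and summarises probes by median polish, so differences in total RNA per cell are removed and small folds are compressed near background. Filters and a genome build are not given in the sources used here, and no coordinates are printed. Groups were taken from the labels. The design text calls the arrays biological triplicates and says no more on whether cultures were separate.

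Probes were named through a table of the platform's annotation, which listed 19086 of the probes; 18511 had 1 gene symbol, 575 had several and were not used, and 17599 were unlisted and are unnamed here. Of the named probes, 18394 matched a gene identifier in a RefSeq gene table of assembly GRCr8, used for names only, and 0 symbols changed. For the 291 genes with more than 1 probe the probe with the highest mean over all arrays was kept, which left 18166 genes. Probes of a gene named in the text are said to disagree where they do.

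A linear model with group as its term was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend in the prior variance; 8 residual degrees of freedom before moderation), giving two-sided moderated tests for 6 comparisons and an F test over groups. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called changed. Errors are SDs over 3 arrays or the model's SEs, and the median SE of a log2 fold change was 0.131. The number of arrays limits the precision. The median log2 fold change of all genes was 0.03, 0.01 and 0.01 at 70 min, 4 h and 8 h.

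Gene lists for 26 pathways, complexes and cell types were fixed before the data were examined, and 458 of their 504 members were tested, matched by symbol, or by synonym where the symbol is not itself current in the gene table; Hspa1a, Hspa1b and Myl2 were among those not tested here. The lists were compared with all other genes by camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 26 lists of a comparison. Also fixed beforehand were the genes to be named: for each comparison with control the 10 higher and 10 lower called genes with the largest change among those whose treated values all lay on one side of the control values and whose mean in the higher group was at or above the median of 5.75; where under 5 passed, also the 5 higher and 5 lower by unadjusted p; up to 4 leading members of each called list, with further members as examples in order of size; and 13 stress and cardiac genes always. Between times the 5 higher and 5 lower were named. Symbols of unnamed loci, olfactory and vomeronasal receptors and small RNAs were passed over, by their prefixes.

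The calculation was tested on simulated data with the real gene means and spreads for the comparison of 70 min with control over 18166 genes. It recovered 98.4% of 64 genes changed by 1 on the log2 scale, 51.6% of 64 changed by 0.5 and 9.2% of 65 changed by 0.3, with 8 false calls for that comparison, and called the 1 list that had been shifted. Overlap between comparisons that share the controls was set beside 100 simulations of unchanged groups. In both kinds of simulation the noise was drawn independently for each gene. The list call was a requirement of the check, and it does not test lists whose members are correlated.

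Alternatives fixed beforehand were the replicate number as a block, eBayes without trend or robust, array weights, a further quantile normalization, centring of arrays, the brighter genes alone, the mean of a gene's probes, all probes, the compared groups alone, a fold of at least 1.5 with or without adjustment, each array left out in turn, and for lists an estimated correlation and fry. Chosen after the data were seen were leaving out the 3 arrays with the highest median and the array median as a covariate. Figures were drawn with matplotlib 3.10.9.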

Results

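The series followed the transcriptome of primary rat cardiomyocytes exposed to SIN-1 (3-morpholinosydnonimine), a compound that releases nitric oxide and superoxide together and so serves as a source of the oxidant peroxynitrite. RNA from control cells and from cells treated for 70 min, 4 h or 8 h was measured on 12 one-colour whole-transcript arrays, 3 in each of 4 groups, described in the design text as biological replicates. The labels give no culture time for the control and do not say whether it received a vehicle, so a fold against control may hold effects of either, and each treated time was compared with the same 3 control arrays. Values are log2 expression, and 18166 named genes were tested. Correlations across genes between arrays of one group ran from 0.9906 to 0.995. The array median over all probes was 5.11 and 5.12 in 70 min replicates 2 and 3 and 5.09 in 4 h replicate 3, against 4.98 to 5.05 in the other arrays. The first principal component, with 33.3% of the variance, placed 70 min replicates 2 and 3 farthest from the controls.

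**Figure D1:**
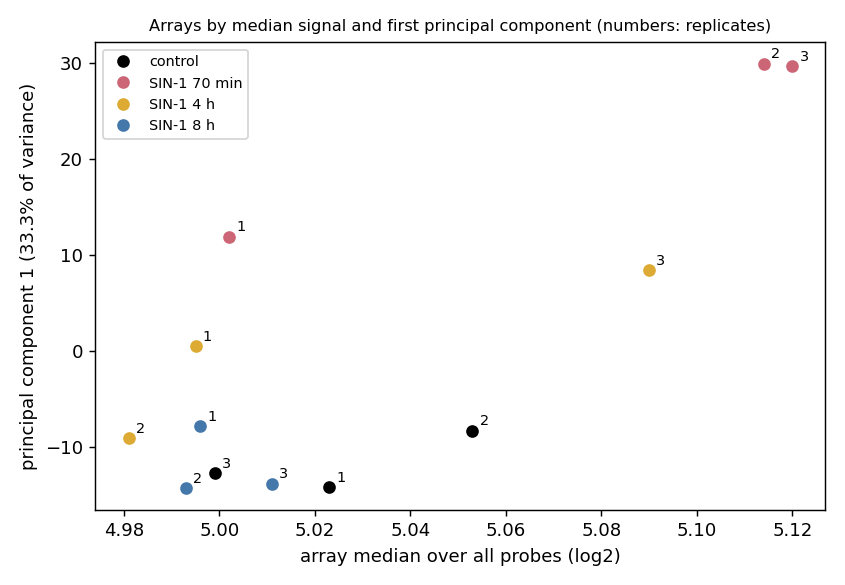
Median log2 signal over all probes of each array (horizontal axis) against its score on the first principal component, which held 33.3% of the variance (vertical axis), coloured by group and numbered by replicate. The 70 min replicates 2 and 3 lie apart at medians of 5.11 and 5.12, and 4 h replicate 3 lies at 5.09.

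The first comparison asked which transcripts differed after 70 min of SIN-1. The highest rises among genes named by the fixed rule, which passes over Olr1 (1.81) for its prefix, were those of the NR4A orphan nuclear receptors, which are immediate early transcription factors. Nr4a1 was 5.19-fold higher (log2 7.78 ± 0.12 against 5.40 ± 0.22, SD, n = 3), Nr4a3 3.85-fold and Nr4a2 3.74-fold. Also higher were Hmga2, a chromatin architectural protein (2.55-fold), Mybl2, a transcription factor of cycling cells (2.54-fold), Id2, an inhibitor of basic helix-loop-helix factors (2.47-fold), the kinase gene Sik1 (2.47-fold), the cytochrome P450 gene Cyp1b1 (2.40-fold), Glb1l2 (2.34-fold) and Egln3, a prolyl hydroxylase of hypoxia-inducible factor (2.31-fold). Among genes that fell, Pi15, a secreted peptidase inhibitor, was 5.87-fold lower and the guidance ligand Sema3a 4.42-fold lower. Edn1, which encodes the vasoconstrictor endothelin, fell from 8.81 ± 0.05 to 6.77 ± 0.18 (SD, n = 3), a 4.11-fold difference. Akr1c14, Epha7, Slc2a12, Sema3d, Omd, Map2k6 and Scara5 were between 3.55-fold and 2.98-fold lower. The largest of the limma adjusted p-values of these 20 genes was 6.7e-05.

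Altogether 2647 of 18166 genes differed from control at 70 min by limma at an adjusted p under 0.05, 1228 higher and 1419 lower, and 739 of them differed by at least 1.5-fold (259 higher, 480 lower). The balance turned with scaling, 46.4% of the called genes being higher here, 51.7% after a further quantile normalization and 55.6% with the array median as a covariate, the last chosen after the data were seen. Without the 3 arrays of highest median, a setting chosen after the data were seen that leaves 1 array at 70 min and takes it to vary like the other groups, 1046 genes were called. Without control replicate 1 the count was 1751, and without control replicate 3 it was 979 higher and 972 lower.

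Stress-response genes behaved unevenly at 70 min. Of 20 measured NRF2 target genes, which encode antioxidant and detoxifying proteins, 5 rose and 2 fell (7 and 2 when adjusted over the list alone). Hmox1, which encodes heme oxygenase, was 2.15-fold higher (log2 fold change 1.10 ± 0.08, SE), and Osgin1 and Gclc were higher by 0.63 and 0.60, while the efflux transporter gene Abcc4 fell by 0.66. Nqo1, at -0.08 ± 0.04 (SE), and Gclm, at 0.12 ± 0.12, did not pass (limma adjusted p = 0.28 and 0.56). As a list the NRF2 targets were not called (camera adjusted p = 0.333; called with the array median as a covariate, 0.0332). Heat shock and chaperone genes were called higher (adjusted p = 0.0184; adjusted p = 0.212 with an estimated correlation), with 5 of 14 rising (6 when adjusted over the list alone), among them Hspd1 (0.54 ± 0.07, SE) and Hspa4 (0.48 ± 0.06). In the unfolded protein response of the endoplasmic reticulum, 4 of 18 rose and 2 fell, 6 and 2 over the list alone (adjusted p = 0.00434; adjusted p = 0.424 with an estimated correlation). The risers were Manf (0.57), Xbp1 (0.55), Edem1 (0.48) and Hspa5 (0.42). Proteasome subunit genes were higher as a list, with 10 of 30 rising and none falling, 15 over the list alone (adjusted p = 2.97e-05; adjusted p = 0.439 with an estimated correlation), and Psmd8 (0.38 ± 0.10, SE) and Psmd12 (0.37 ± 0.06) led. The ATF4 list, of amino acid and integrated stress response genes, moved both ways, with 6 of 27 higher and 4 lower (adjusted p = 0.819), while Slc7a1 rose by 0.67 and Ddit3 fell by 0.68. Without 70 min replicate 1 the chaperone and unfolded protein response calls ended (adjusted p = 0.164 and 0.0833), the chaperone call also ended with the mean of all probes of a gene (0.0543), and the call of Psmd8 ended without control replicate 2 or 70 min replicate 2 (0.0537 and 0.0568).

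Immediate early genes divided at 70 min into 7 that rose and 10 that fell of 29. Beside the NR4A genes, Klf4 (1.02 ± 0.10, SE) and Fosl1 (0.74 ± 0.12) rose. Egr1 fell by 1.38, Ccn1 by 1.21, Dusp1 by 1.18 and Fos by 0.60, whereas Atf3 stood at -0.03 ± 0.13 (limma adjusted p = 0.91). The call of Fos ended without control replicate 2 (adjusted p = 0.0513) or 70 min replicate 3 (0.0504). The list was not called (camera adjusted p = 0.819). Among MAP kinase feedback genes, 5 of 12 rose and 2 fell (adjusted p = 0.275), with Etv5 at 0.93 and Spred2 at 0.82.

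Metabolic lists moved in different directions at 70 min. Of 14 measured cholesterol synthesis genes, 9 fell and none rose, 10 fell over the list alone (camera adjusted p = 8.88e-07; adjusted p = 0.133 with an estimated correlation). Fdps fell by 1.04, Idi1 and Dhcr7 by 0.69 each and Fdft1 by 0.67. Of 24 genes of fatty acid oxidation and PPAR targets, 9 fell and 1 rose, 10 and 1 over the list alone (adjusted p = 0.000325; adjusted p = 0.212 with an estimated correlation); Acadm fell by 0.75, Pdk4 and Ech1 by 0.73 and Eci1 by 0.62, and Ucp3 rose by 0.55. Hypoxia and glycolysis genes were called higher, with 7 of 18 rising and 2 falling, 8 and 2 over the list alone (adjusted p = 0.000579; adjusted p = 0.212 with an estimated correlation). Besides Egln3, Hk2, a hexokinase gene, was 2.24-fold higher and the glucose transporter gene Slc2a1 1.53-fold higher, while Ndrg1 fell by 0.48 and Adm by 0.41. No member of the 25 oxidative phosphorylation subunit genes passed (adjusted p = 0.819).

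Cell cycle genes were called higher at 70 min, with 9 of 26 rising and none falling, and 9 over the list alone (camera adjusted p = 0.000257; adjusted p = 0.424 with an estimated correlation). The risers were largely components of DNA replication. Mcm5 was 2.08-fold higher, Mcm6 1.91-fold, Pcna and Mcm4 1.78-fold each. Fibroblast and matrix marker genes, fixed as markers of a cell type that cardiomyocyte cultures can hold, were called lower, with 6 of 18 falling, and 8 falling and 1 rising over the list alone (adjusted p = 0.00119; adjusted p = 0.212 with an estimated correlation). Lum fell by 1.42, Dcn by 1.05, Mmp2 by 0.51 and Col3a1 by 0.41. Of the other cell type markers, endothelial genes had 2 of 11 higher and 1 lower (adjusted p = 0.608), smooth muscle and pericyte genes 1 of 10 higher and 1 lower (adjusted p = 0.819), and macrophage and leukocyte genes 0 of 16 changed (adjusted p = 0.819). Sarcomere and cardiomyocyte markers had 1 of 17 higher, Myoz2 at 0.62 (adjusted p = 0.129; called without 70 min replicate 1, 0.0377).

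The remaining lists were not called at 70 min. Members that passed were 3 of 15 lower for the interferon response (camera adjusted p = 0.0863), 1 of 17 higher and 3 lower for p53 targets (0.608), 2 of 24 lower for NF-kB and inflammatory genes (0.999), 1 of 5 higher for metallothionein and zinc genes (0.608), 1 of 12 higher and 4 lower for the nitric oxide and cGMP pathway (0.468), 3 of 15 higher and 3 lower for base excision repair and PARP genes (0.819), 3 of 14 higher and 2 lower for clock genes (0.999), 1 of 10 lower for hypertrophy and fetal programme genes (0.899), and 2 of 17 higher and 1 lower for calcium handling and ion channel genes (0.819). In the nitric oxide pathway, Ddah2 and Ddah1, whose products break down the nitric oxide synthase inhibitor dimethylarginine, moved apart, Ddah2 falling by 1.17 and Ddah1 rising by 0.68. Gdf15 rose by 0.53, Nppa stood at 0.37 ± 0.13 (SE), and Nppb, Nos2 and Cdkn1a at 0.07, 0.25 and 0.13, none of these last 4 passing. The call of Gdf15 ended without control replicate 3 (adjusted p = 0.0513), Nppa passed without 70 min replicate 1 (0.0341), without the trend in the prior variance (0.0383) and with array weights (0.0304), and the interferon list was called without 70 min replicate 2 (0.0326). That list was also called among the brighter genes (median -0.52 against -0.11, adjusted p = 0.0162) and by fry (0.00198). Adjusted over the list alone, the uncalled lists whose counts differed were, besides the NRF2 targets, p53 targets (3 higher, 4 lower), immediate early genes (8 and 10), MAP kinase feedback genes (6 and 3), clock genes (3 and 3), hypertrophy genes (3 and 1) and smooth muscle markers (1 and 2). Of the 8 lists called at 70 min, none held with an estimated correlation, where 6 of all 26 lists, called or not, had an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way on balance, 11 were called. For the immediate early, NF-kB, base excision repair and clock lists the median and mean lay above 0 while camera, which compares with all other genes, pointed lower, and for calcium handling genes the median alone lay below 0. Another division of the same 6 arrays, with control replicates 1 and 2 and 70 min replicate 3 on one side, called 9 lists.

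**Figure D2:**
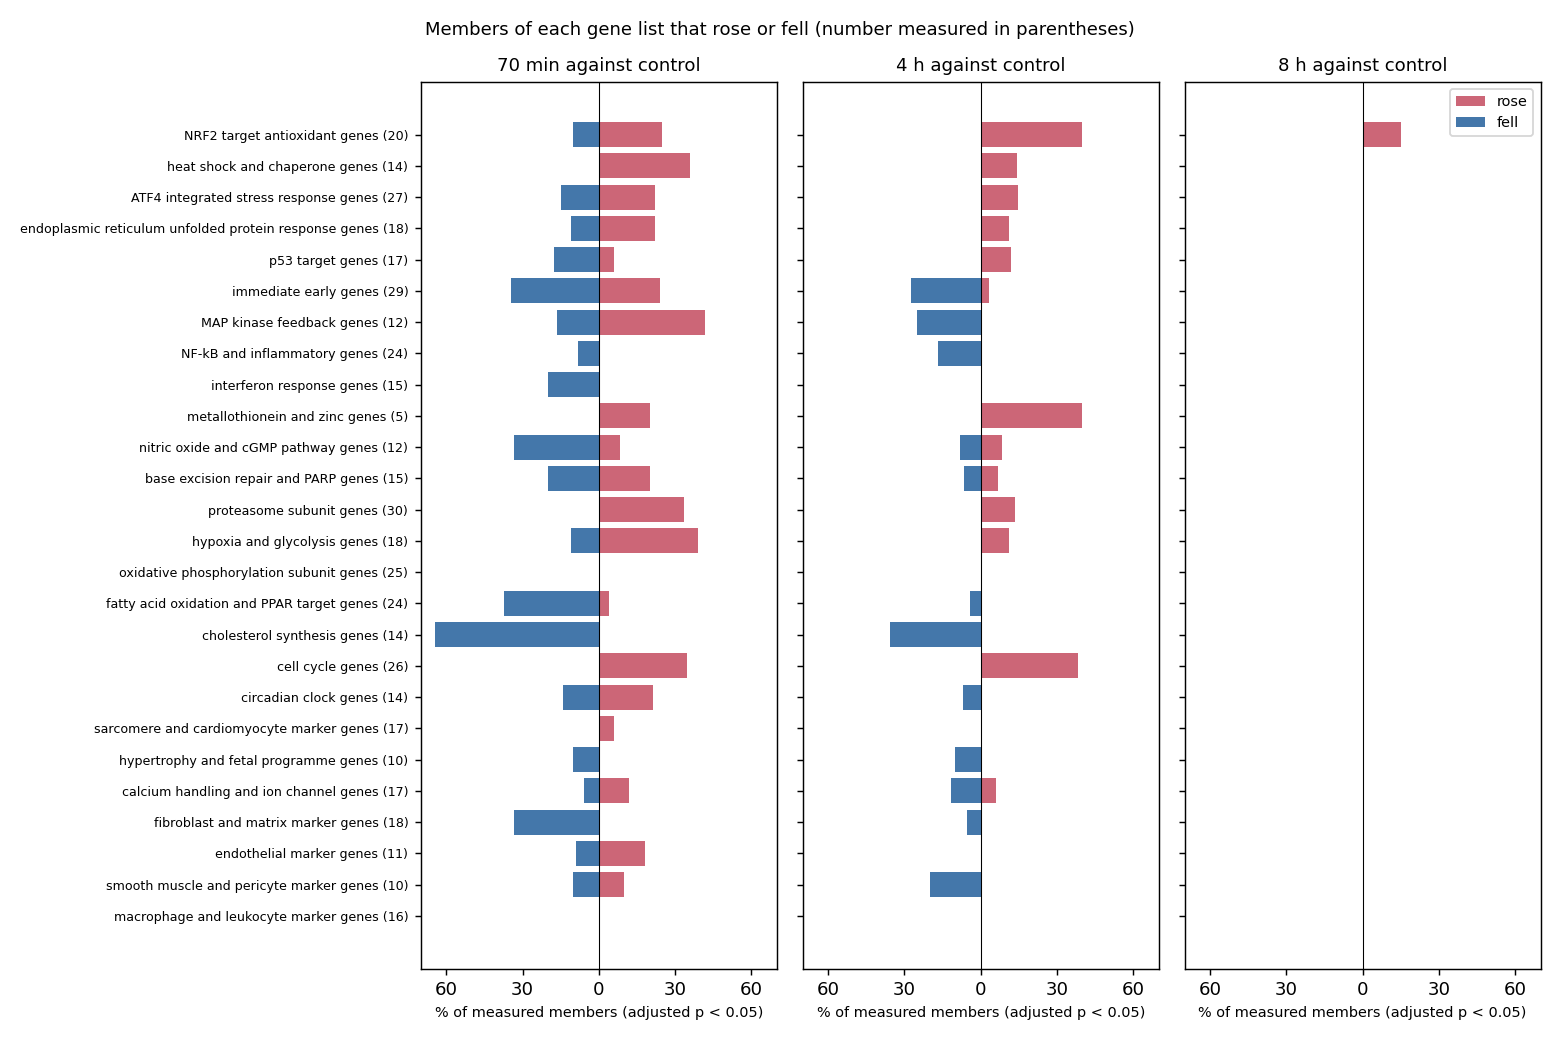
Percent of the measured members of each of the 26 gene lists that rose (right of 0) or fell (left of 0) at a limma adjusted p under 0.05, at 70 min, 4 h and 8 h against control, with the number measured in parentheses. Of 14 cholesterol synthesis genes 9 fell at 70 min and 5 at 4 h, of 20 NRF2 targets 8 rose at 4 h, and at 8 h 3 NRF2 targets were the list members that passed. With an estimated correlation the cholesterol list at 70 min and the NRF2 list at 4 h were not called (adjusted p = 0.133 and 0.0612).

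After 4 h of SIN-1 the leading genes were different in part. Cyp1a1, a cytochrome P450 gene and classical target of the aryl hydrocarbon receptor, was 3.40-fold higher (log2 fold change 1.77 ± 0.15, SE), and Ahrr, the repressor of that receptor, 1.81-fold. The control values of Cyp1a1 were low (4.451, 4.509 and 4.853), near the median of 4.34 of unnamed probes, where folds are less certain. Its values at 4 h were 6.431, 6.495 and 6.187. The histone genes H1f5, H2ac4, H2ac12 and Hist1h2af were 2.20-fold to 1.88-fold higher, and near-identical histone copies can share probe signal. The call of Hist1h2af ended without control replicate 1 or 2 (adjusted p = 0.096 and 0.142), without 4 h replicate 1 or 2 (0.0986 and 0.0712), and without the trend or with a robust prior (0.0965 and 0.113). Mybl2, Dtl, a replication-linked ubiquitin ligase adaptor, Glb1l2 and the pro-apoptotic gene Bcl2l11 were 1.87-fold to 1.76-fold higher. Ankrd1, a stretch- and stress-responsive cardiac repeat protein, fell 2.59-fold, from 9.12 to 7.74, and Egr1 was 2.56-fold lower. Rgs4, Pkib, Edn1, Adgrl3, Epha2, Gdf6, Cemip and Nuak1 were between 2.39-fold and 1.94-fold lower. The probes of Pkib went the same way but by unequal amounts, -1.22 and -0.27, and the mean of both did not pass (limma adjusted p = 0.0618). Its call also ended without control replicate 1 or 2 (0.0691 and 0.0934) or 4 h replicate 1 (0.069), and without the trend or with a robust prior (0.0635 and 0.107).

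At 4 h limma called 699 of 18166 genes, 378 higher and 321 lower, and 178 of these differed by at least 1.5-fold (72 higher, 106 lower). The balance turned here too, 54.1% of the called genes being higher, 47.3% with arrays centred on their medians (259 higher, 288 lower) and 45.4% without the trend in the prior variance (154 and 185). It was 45% without control replicate 2, 45.8% and 47.6% without 4 h replicate 1 or 2 and 49.7% with the compared groups alone. The count was 339 without the trend in the prior variance, and 380, 373, 444 and 437 without control replicate 1, 2 or 3 or 4 h replicate 1.

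NRF2 targets were called higher at 4 h, with 8 of 20 rising and none falling, 9 when adjusted over the list alone (camera adjusted p = 2.51e-09; adjusted p = 0.0612 with an estimated correlation). Gclc, the catalytic subunit of glutamate-cysteine ligase, was 1.56-fold higher, Hmox1 1.43-fold, Osgin1 1.42-fold and Nqo1 1.39-fold (0.48 ± 0.04, SE). The call of Osgin1 ended without control replicate 1 or 2 (adjusted p = 0.101 and 0.115) or 4 h replicate 1 or 2 (0.0825 and 0.0864). Abcc4, which had fallen at 70 min, rose by 0.37. Gclm was at 0.26 ± 0.12 (limma adjusted p = 0.32). Metallothionein and zinc genes were higher, with 2 of 5 rising, 3 over the list alone (adjusted p = 0.00379; adjusted p = 0.0612 with an estimated correlation), Mt1 by 0.73 and Mt2A by 0.38, and the probes of each agreed in direction. Proteasome subunit genes had 4 of 30 higher (17 when adjusted over the list alone; adjusted p = 4.59e-10; adjusted p = 0.149 with an estimated correlation), Psmc1 at 0.26 and Psmd1 at 0.25, while Psmd3 and Psmd8 at 0.26 each did not pass. The call of Psmc1 ended without control replicate 1 or 2 (0.0794 and 0.0532) or 4 h replicate 1 or 3 (0.0537 each), and that of Psmd1 without control replicate 2 (0.0557). Unfolded protein response genes had 2 of 18 higher, 4 over the list alone (adjusted p = 0.000168; adjusted p = 0.149 with an estimated correlation). Those that passed were Hspa5 at 0.23 and Pdia6 at 0.21, and the larger values of Sdf2l1, Edem1 and Xbp1 (0.28, 0.27 and 0.26) did not. Among p53 targets 2 of 17 rose, 3 over the list alone, Cdkn1a by 0.41 and Gadd45a by 0.39, and Polk at 0.40 did not pass (adjusted p = 0.0331; adjusted p = 0.149 with an estimated correlation); that call was lost without control replicate 2 or 3 (0.0622 and 0.0751) and without 4 h replicate 1 or 2 (0.0845 and 0.108), after a further quantile normalization (0.0602) and with the array median as a covariate (0.0528). Without the trend in the prior variance, Osgin1, Psmc1 and Psmd1 did not pass (0.0537, 0.115 and 0.108). Xbp1 and Psmd3 passed among the brighter genes (0.0354 and 0.0411). Xbp1 passed also with array weights and with a robust prior (0.0278 and 0.0431).

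Cell cycle genes were again called higher at 4 h, with 10 of 26 rising, 13 over the list alone (camera adjusted p = 7.03e-13; adjusted p = 0.0662 with an estimated correlation), Mcm6 by 0.80, Mcm5 by 0.72 and Pcna by 0.65, while fibroblast markers were called lower with 1 of 18 falling, 3 over the list alone (adjusted p = 0.00279; adjusted p = 0.149 with an estimated correlation). Col3a1 fell by 0.18, a call that ended without control replicate 3 or 4 h replicate 1 (0.0607 and 0.0528) or the trend (0.264), and Dcn, Lum and Mmp2 at -0.44, -0.32 and -0.29 did not pass. After a further quantile normalization Lum and Mmp2 passed (0.0475 and 0.0467). Lum passed also with array weights and with the compared groups alone (0.0428 and 0.0261), and Mmp2 among the brighter genes and without control replicate 2 (0.0408 and 0.0369). Cholesterol synthesis genes were called lower with 5 of 14 falling (9 over the list alone), and that call held with an estimated correlation (adjusted p = 7.31e-09; adjusted p = 0.0383 with an estimated correlation); Fdps fell by 0.81 and Lss by 0.55. The MAP kinase feedback list, of phosphatases and sprouty proteins that MAP kinase signalling induces, was also lower under both (adjusted p = 2.13e-06; adjusted p = 0.0383 with an estimated correlation). In it 3 of 12 fell, 7 over the list alone, Dusp6 by 1.08, Phlda1 by 0.88 and Spry2 by 0.63. Immediate early genes were called lower, with 8 of 29 falling and 1 rising, 11 and 2 over the list alone (adjusted p = 0.000107; adjusted p = 0.0822 with an estimated correlation). Fos and Dusp1 fell by 0.78 each and Myc by 0.65, and Csrnp1 rose by 0.45. NF-kB and inflammatory genes were called lower with 4 of 24 falling, 5 over the list alone (adjusted p = 0.00169; adjusted p = 0.0612 with an estimated correlation), Il6 by 0.77 and Ccl2 by 0.69. The call of Ccl2 ended without control replicate 1, 2 or 3 (0.0694, 0.0676 and 0.0813) or 4 h replicate 2 or 3 (0.0669 and 0.0704), and without the trend (0.0591). Clock genes were called lower with 1 of 14 falling, 5 over the list alone (adjusted p = 0.0152; adjusted p = 0.103 with an estimated correlation). Dbp fell by 0.36, and Ciart and Per2 at -0.48 and -0.43 did not pass, except among the brighter genes (0.0347 and 0.0492) and, for Ciart, after a further quantile normalization (0.0495) or with the compared groups alone (0.032).

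The 14 lists not called at 4 h had camera adjusted p-values of 0.0518 (hypoxia and glycolysis) to 0.758 (endothelial markers). The hypoxia list was called without control replicate 1 or 3 (0.0269 and 0.0305) or 4 h replicate 3 (0.0202), and with the replicate block (0.0435). The passing members of these lists were 2 of 18 higher for hypoxia and glycolysis, 1 of 24 lower for fatty acid oxidation, 4 of 27 higher for ATF4 genes, 2 of 14 higher for chaperones, 1 of 12 higher and 1 lower for the nitric oxide pathway, 1 of 15 higher and 1 lower for base excision repair, 1 of 10 lower for the fetal programme (Ankrd1), 1 of 17 higher and 2 lower for calcium handling and 2 of 10 lower for smooth muscle markers. No member passed by limma in the oxidative phosphorylation, interferon, sarcomere, endothelial and macrophage lists. For hypertrophy genes the median lay above 0 and the mean and camera below. Of the 12 lists called, 2 held with an estimated correlation, fry called 16, and a division with control replicates 1 and 2 and 4 h replicate 3 on one side called 10. Atf3, Nppa, Nppb, Gdf15 and Nos2 stood at 0.18, 0.23, -0.05, 0.25 and 0.15 and did not pass.

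**Figure D3:**
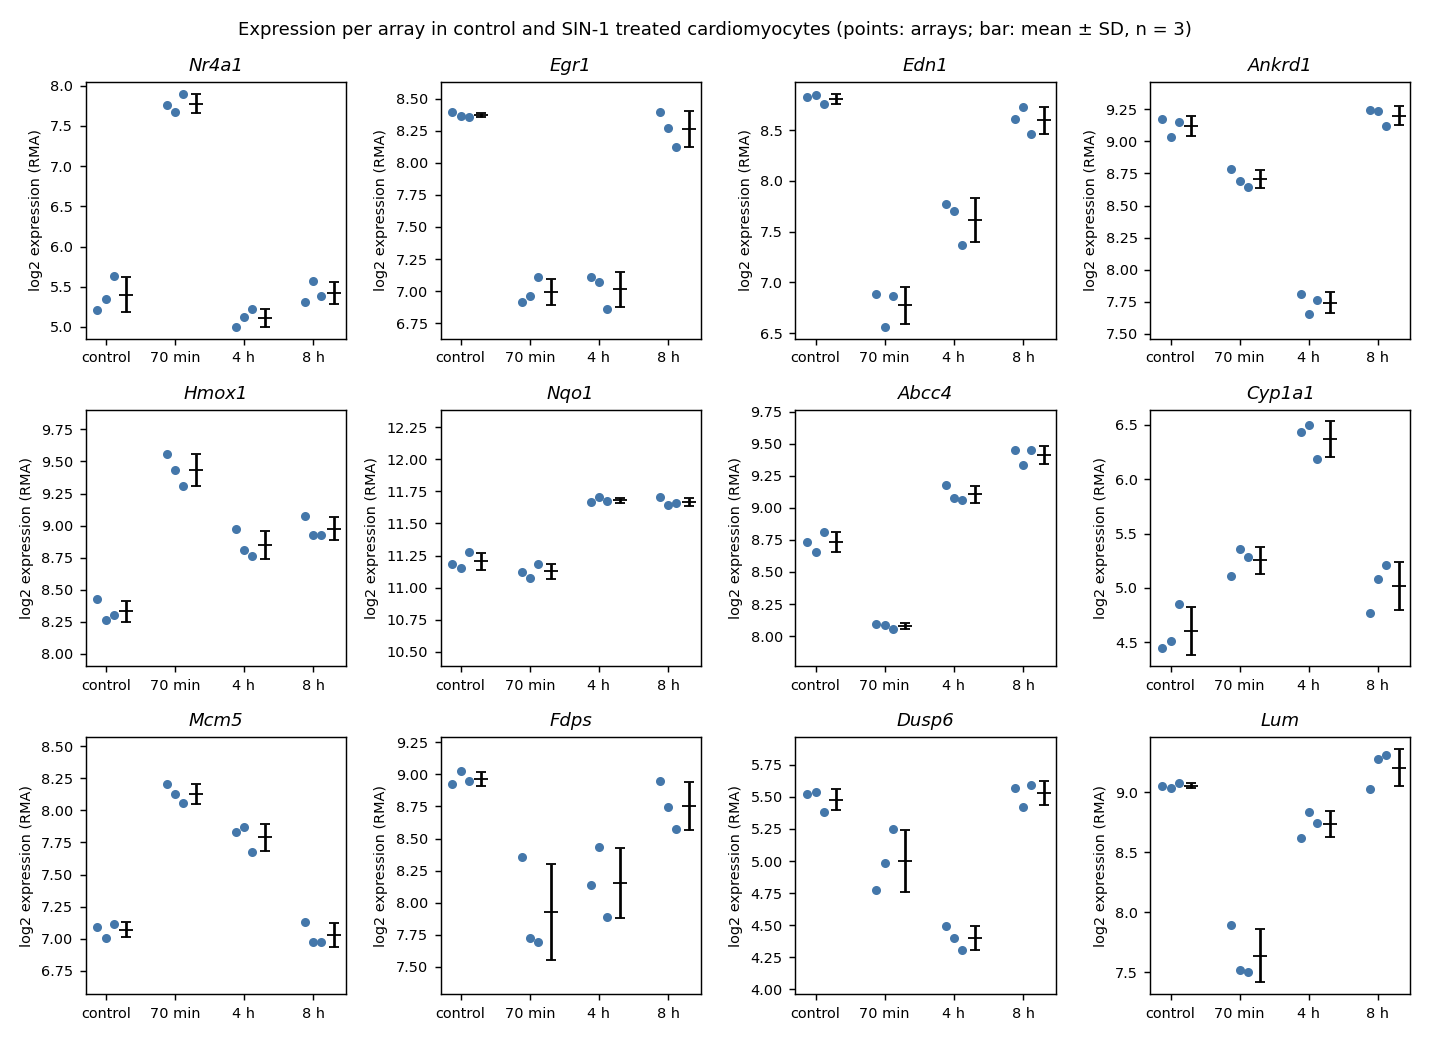
Log2 expression (vertical axes) of 12 genes in control cells and after 70 min, 4 h and 8 h of SIN-1, with a point per array and bars of mean ± SD (n = 3); the genes plotted were chosen after their values were seen. Nr4a1 was at 7.78 at 70 min against 5.40 in control and 5.11 at 4 h, Ankrd1 was lowest at 4 h (7.74), and Abcc4 moved from 8.08 at 70 min to 9.41 at 8 h.

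By 8 h, 5 of 18166 genes differed from control by limma, and 993 had an unadjusted p under 0.05. The 4 higher genes were Abcc4, 1.6-fold (0.68 ± 0.07, SE), Ptgr1, an enzyme that reduces reactive lipid aldehydes and ketones, 1.57-fold (0.65 ± 0.08), Hmox1, 1.56-fold (0.64 ± 0.08), and Nqo1, 1.38-fold (0.47 ± 0.04). The lower gene was Olr1, the oxidised low-density lipoprotein receptor, at -1.0 ± 0.11 (SE; limma adjusted p = 0.000551). It was named after its values were seen, because the naming rule passes over symbols with that prefix. The count was 2 without the trend in the prior variance, where Ptgr1, Hmox1 and Nqo1 did not pass (adjusted p = 0.0536, 0.0825 and 0.128), and 37 with array weights. The next genes by unadjusted p, which did not pass, were Mt2A at 0.28 and H4c14, Fv1, Elovl6, Idi1 and Ccn4 at -0.63, -0.89, -0.61, -0.65 and -0.26; the probes of Fv1 disagreed in sign (0.12 and -0.89). With array weights these 6 passed (adjusted p of 0.00223 to 0.0231), and with the replicate block Mt2A, H4c14 and Fv1 did (0.0333, 0.0333 and 0.00936), the last 2 also with the compared groups alone (0.0196 and 0.0426).

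NRF2 targets were called higher at 8 h and kept that call with an estimated correlation (camera adjusted p = 2.48e-22; adjusted p = 0.0181 with an estimated correlation). All 20 measured members had a positive log2 fold change, 3 passed over all genes and 11 when adjusted over the list alone, and the median was 0.23. The other lists called at 8 h had no member that passed over all genes. Cholesterol synthesis genes were lower (adjusted p = 3.22e-06; adjusted p = 0.095 with an estimated correlation), with 2 of 14 falling when adjusted over the list alone and Idi1 at -0.65 and Insig1 at -0.44. Higher lists were proteasome subunits (adjusted p = 0.00262; 0.565 as adjusted p with an estimated correlation), metallothionein and zinc genes (0.0161; 0.13), oxidative phosphorylation (0.0181; 0.596), fatty acid oxidation and PPAR targets (0.019; 0.517) and ATF4 genes (0.0397; 0.565), the first value of each pair being the adjusted p with the preset correlation and the second that with an estimated one. NF-kB and inflammatory genes were lower (adjusted p = 0.0486; adjusted p = 0.337 with an estimated correlation). These calls were sensitive to single arrays and to the processing. Without control replicate 1 those of NF-kB, oxidative phosphorylation and fatty acid oxidation ended (adjusted p = 0.131, 0.0767 and 0.0801). Without control replicate 2 these and those of ATF4 and proteasome genes ended (0.0645 to 0.291), which left 3 lists, and without control replicate 3 those of NF-kB and metallothionein genes (0.0636 each). Leaving out 8 h replicate 1 ended the ATF4, oxidative phosphorylation and fatty acid oxidation calls (0.219, 0.404 and 0.0727) and called chaperones and immediate early genes (0.0378 and 0.0168). Leaving out 8 h replicate 2 left 3 lists, with values of 0.0733 to 0.118 for the ATF4, NF-kB, metallothionein, oxidative phosphorylation and fatty acid oxidation calls that ended, and leaving out 8 h replicate 3 ended the NF-kB and metallothionein calls (0.319 and 0.0696). The NF-kB call also ended with the replicate block (0.0615), a further quantile normalization (0.0588), the mean of all probes (0.0553), the brighter genes (0.433, median 0.025) and the array median as a covariate (0.119). Quantile normalization ended the ATF4 call as well (0.0716), and the mean of all probes that of metallothionein genes (0.0688). The brighter genes ended the ATF4, oxidative phosphorylation and fatty acid oxidation calls (0.179, 0.0827 and 0.0602). The covariate ended these and the proteasome call (0.148, 0.169, 0.147 and 0.119). Array weights called chaperones (0.0319) and the covariate cell cycle genes, lower (0.0196). The other 18 lists had adjusted p-values of 0.0688 (chaperones) to 0.977 (macrophage markers), and Fos, Egr1, Atf3, Nppa, Nppb, Gdf15, Nos2, Gclm and Cdkn1a did not pass (adjusted p of 0.65 or more). Of the 8 lists called, 1 held with an estimated correlation, fry called 2, and a division with control replicates 1 and 2 and 8 h replicate 3 on one side called 5. For p53, MAP kinase feedback and sarcomere genes the median lay above 0 and the mean and camera below, for macrophage markers the reverse, and the mean of interferon genes was 0.

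Direct comparisons between times set the treated groups against each other. No control is given for each time, so these differences may also hold effects of time in culture. From 70 min to 4 h, 1386 genes differed by limma, 814 higher at 4 h and 572 lower. Pi15 was 5.15-fold, Bcl2l11 3.59-fold, Epha7 3.05-fold, Map2k6 3.00-fold and Slc2a12 2.87-fold higher at 4 h than at 70 min, and Nr4a1 was 6.33-fold, Nr4a3 3.21-fold, Lmcd1 3.16-fold, Nr4a2 2.99-fold and Frmd4a 2.82-fold lower. From 4 h to 8 h, 637 genes differed, 358 higher and 279 lower. Ankrd1 was 2.74-fold, Egr1 2.38-fold, Adgrl3 2.33-fold, Cemip 2.04-fold and Phlda1 2.02-fold higher at 8 h, whereas Cyp1a1 (2.55-fold), H1f5, H2bc8, H4c14 and H2ac4 (2.21-fold to 2.15-fold) were lower. Between 70 min and 8 h, 2904 genes differed, 1736 higher at 8 h and 1168 lower, led by Sema3a, Akr1c14, Map2k6, Pi15 and Edn1 (4.16-fold to 3.54-fold higher) and by Nr4a1, Nr4a2, Nr4a3, Hmga2 and the replication licensing gene Cdc6 (5.12-fold to 2.79-fold lower). Olr1, which the naming rule passes over, stood at -2.23 from 70 min to 4 h. From 70 min to 8 h it stood at -2.82, a larger fall than that of Nr4a1. With the array median as a covariate the balance turned in all 3, 46.6% of the called genes being higher from 70 min to 4 h (58.7% here), 49% from 4 h to 8 h (56.2% here) and 47.8% from 70 min to 8 h (59.8% here). From 4 h to 8 h it also turned without 4 h replicate 3 (46.4%) and without the 3 arrays of highest median (47.7%), and from 70 min to 8 h without those 3 arrays (49.6%). The F test over the 4 groups called 2775 genes. Without the 3 arrays of highest median, chosen after the data were seen, the counts were 318 from 70 min to 4 h, 1181 from 70 min to 8 h and 1205 for the F test; without 70 min replicate 3 and without 4 h replicate 2 the 70 min to 4 h count was 885 and 909, and without 8 h replicate 2 the 4 h to 8 h count was 299. The gene lists were also compared between times, and camera called 10 from 70 min to 4 h, 10 from 4 h to 8 h and 9 from 70 min to 8 h. Of these, 1, 0 and 0 held with an estimated correlation. With it 4, 4 and 2 of all 26 lists, called or not, had an unadjusted p under 0.05. The one that held was the MAP kinase feedback list, with 6 of 12 lower and 1 higher at 4 h than at 70 min (adjusted p = 6.29e-07; adjusted p = 0.0223 with an estimated correlation). In lists called between times, the median of immediate early genes alone lay below 0 from 4 h to 8 h (-0.002), where the mean and camera pointed higher.

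The genes called at 70 min were followed at the later times. The 1228 genes higher at 70 min had median log2 fold changes of 0.44 at 70 min, 0.21 at 4 h and 0.05 at 8 h, and the 1419 lower ones -0.48, -0.17 and 0.01; medians of genes picked at 70 min shrink at other times in part through that choice. In the direct comparisons with 70 min, 384 of the first and 586 of the second were called toward control at 4 h, 3 and 7 away from it, and 864 and 1129 toward control at 8 h. These counts use the 70 min arrays that picked the genes, which favours a return. Of the 699 genes called at 4 h, 460 had been called in the same direction at 70 min, 262 higher and 198 lower, where independent lists would share 25.6 and 25.1. Another 37 went the opposite way. Fold changes at 70 min and 4 h correlated across genes at 0.561, against 0.5 simulated, with a covariance of 0.0309 against 0.0094 simulated; genes are not independent replicates, and with 3 controls, too few to divide so that each comparison has its own, part of the overlap may come from the shared controls. For 4 h and 8 h the correlation was 0.408 against 0.5 simulated and the covariance 0.0118 against 0.0094, with all 5 genes called at 8 h also called at 4 h in the same direction, and for 70 min and 8 h these were 0.232 against 0.5 and 0.0095 against 0.0094, with 1 gene called in the same direction and 3 in opposite directions.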

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

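Tests chosen after the result was seen were the array median as a covariate, the fibroblast list and the spread of the mitotic genes; the splits, the left-out pairs and the bounds for the further replication and mitotic genes were set out before their results were seen, the last after the rise of cell cycle genes was known.

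The change from the shared control differed between times for 1386 genes (4 h against 70 min), 637 (8 h against 4 h) and 2904 (8 h against 70 min), each by a limma test of the difference. Effects of time in culture may be part of these differences. Between 70 min and 4 h, 37 genes were called in opposite directions. Of the genes named, Bcl2l11 went from -1.03 at 70 min to 0.81 at 4 h, Gadd45a from -0.42 to 0.39 and Trib3 from -0.32 to 0.39. The reverse course was taken by Frmd4a (1.02 to -0.48), Lmcd1 (0.86 to -0.80), Phlda1 (0.60 to -0.88) and Ccn4 (0.21 to -0.24). Between 70 min and 8 h, 3 genes were called in opposite directions: Abcc4 went from -0.66 at 70 min to 0.37 at 4 h and 0.68 at 8 h, and Ptgr1 from -0.41 to 0.39 and 0.65. The remaining one, Olr1, chosen after its values were seen, went from 1.81 to -0.41 and -1.0. Outside the named genes, of 17599 unnamed probes 201 were higher than control and 254 lower at 70 min, 49 and 53 at 4 h, and 2 and 0 at 8 h; at 70 min this was 2.59% of unnamed probes, against 9.26% of named ones.

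For each of the 6 counts of changed genes the real grouping was the 1 of 10 splits of its 6 arrays with a count as large. The real values of 2647, 699, 5, 1386, 637 and 2904 stood against highest others of 0, 0, 0, 150, 0 and 0, in the order of 70 min, 4 h and 8 h against control, 4 h against 70 min, 8 h against 4 h and 8 h against 70 min; 10 splits are too few for a share under 0.05. The F test count of 2775 was reached by 1 of 100 splits of the 12 arrays, the real one, with a highest other of 1133. That argues against chance for the F test count, which does not tell which time differs. The counts of lists called by camera with the preset correlation stood closer to other splits. At 70 min 2 of 10 splits called as many as the real 8, and the split with control replicates 1 and 2 and 70 min replicate 3 on one side called 9. At 4 h the real 12 stood against 10 (1 of 10 splits as large) and at 8 h 8 against 5 (1 of 10), again too few splits for a share under 0.05. In all 3 comparisons the split with the highest other count set control replicates 1 and 2 with the treated replicate 3.

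The first pattern weighed was the large count at 70 min while 70 min replicates 2 and 3 had the highest array medians, and genes called from these replicates and 2 controls were looked up in 70 min replicate 1 against the left-out control. Among genes at or above the median signal at least 89% went the same way, whichever control was left out, which argues against a shift confined to the 2 arrays. Their median change in replicate 1 was smaller, 0.33 to 0.412, against 0.521 to 0.525 in the arrays that called them. With replicate 2 or 3 left out instead it was 0.468 to 0.549. Part of the change may thus be particular to replicates 2 and 3, which was not tested. Among dimmer genes the lowest share was 60.6% (74.7% and 75.5% with the other controls left out), between what a shift and a shared change predict, so for dim genes an array-wide shift and a treatment effect cannot be told apart. By direction, dim genes called higher agreed in 68.4%, 54.2% and 72.3%, with control replicate 1, 2 or 3 left out. Those called lower agreed in 86.7%, 77.1% and 82.8%. With the array median as a covariate, 75.2% of the 2647 genes were still called in the same direction, which argues against the median as the whole cause. A response to SIN-1 may account for most changes of bright genes at 70 min; a culture-time or handling difference from the control, whose time is not given, was not tested.

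The second pattern was the rise of cell cycle genes at 70 min and 4 h, where the 8 replication genes of the list (8 and 7 rose) had medians of 0.806 and 0.605 and its 18 mitotic genes (1 and 3 rose) 0.052 and 0.206, a division made after the values were seen. A larger share of proliferating non-myocytes would raise both alike, which was also tested on 26 further replication and 36 further mitotic genes from no earlier list: their medians differed by 0.294 at 70 min (0.34 and 0.04; two-sided permutation test over genes with 100000 draws, p = 1e-05, the smallest these draws can give, adjusted over 3 times 3e-05) by 0.153 at 4 h (permutation p = 0.00062, adjusted 0.00093) and by 0.099 at 8 h, when none of them rose (permutation p = 0.026, adjusted 0.026). At 70 min the mitotic genes lay near the median of all genes (0.03). In the list they lay 0.754 below the replication genes (SD 0.248), but that gap was favoured by the division made after the values were seen. Among further genes they lay 0.294 below (SD 0.241), just over their spread, a rule chosen after the result was seen. That SD is a spread between genes and not an error of the difference. So narrow a margin does not decide whether such a share was the whole cause. Further replication genes did rise more often at 70 min, 12 of 26 against 1 of 36 mitotic genes. By the test set out beforehand the share stays open, since 0.294 lies between the bounds set for and against it. At 4 h the difference exceeded the spread in the list (0.4, SD 0.199) but not among further genes (0.153, SD 0.18), where it lay within the range that a larger share predicts, so such a share may contribute there, beside a rise of replication genes within cells already in the culture, which was not tested; genes are not independent. The fibroblast list, which a larger share of fibroblasts would raise, was lower at both times (camera adjusted p no higher than 0.00279). However, neither call held with an estimated correlation. Its most abundant members did not fall with it. Col1a1 and Fn1, at 12.7 and 12.8 in controls, had log2 fold changes of 0.01 and 0.07 at 70 min and 0.03 and 0.07 at 4 h. Whether signals that high can show a small change in share was not tested. As the members moved unequally, the list does not decide whether the share of fibroblasts changed.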

How the results depend on the processing

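Leaving out the 3 arrays with the highest median and the array median as a covariate were chosen after the data were seen. Named genes were not refitted in either of these settings, and gene lists were not refitted without the 3 arrays. In the alternatives applied to them, no called list or named gene changed its tested direction. The median of the NF-kB list at 8 h went from -0.06 to 0.025 among brighter genes. Of 1164 alternative values for gene lists, 1071 kept their side of the threshold, 74 lost a call and 19 gained one. Most of these values belong to lists that were not called, since 8, 12 and 8 of 26 were called at 70 min, 4 h and 8 h. The share kept thus overstates how stable the calls were. Leaving out single arrays ended a list call 2, 4 and 20 times at these times. For named genes 3034 values were kept, 53 lost a call and 33 gained one, of 3120.

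Where counts moved by over 1.5 times the values were as follows, and where neither fewer genes or arrays nor a stricter threshold explains them the cause was not tested. Without the 3 arrays of highest median, where the lone 70 min array is taken to vary like the other groups, 1046 genes were called at 70 min (57.4% higher, against 46.4%), 318 for 4 h against 70 min, 1181 for 8 h against 70 min (49.6% higher, against 59.8%) and 1205 by the F test. A fold of at least 1.5 left 739 at 70 min (35% higher), 178 at 4 h (40.4% higher, against 54.1%), 396 for 4 h against 70 min, 149 for 8 h against 4 h and 758 for 8 h against 70 min; with an unadjusted p it gave 791, 236, 68 at 8 h (17.6% higher, against 80%), 427, 200 and 782. Without the variance trend 339 genes were called at 4 h, 2 at 8 h and 315 for 8 h against 4 h. Over all probes 454 were called at 4 h and 921 for 4 h against 70 min. Array weights gave 37 at 8 h. Fitting the compared groups alone gave 763 for 4 h against 70 min and 330 for 8 h against 4 h. With the array median as a covariate 1929 were called for 8 h against 70 min (47.8% higher). Its other counts moved by less, but the balance turned for 2293 genes at 70 min (55.6% higher) and 1082 for 4 h against 70 min (46.6% higher, against 58.7%).

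Leaving out each array in turn gave 1751 to 3106 genes at 70 min, 373 to 575 at 4 h, 885 to 1799 for 4 h against 70 min, 299 to 504 for 8 h against 4 h, and 3 to 7 lists at 8 h. At 8 h, 5 to 6 genes were called. With an estimated correlation camera called 0, 2 and 1 lists at 70 min, 4 h and 8 h (6, 8 and 3 at an unadjusted p under 0.05). At 8 h the brighter genes gave 4 lists, the covariate 4 and fry 2. Taking unadjusted p under 0.05 in both comparisons, 1623 genes overlapped in direction for 70 min and 4 h, 327 for 70 min and 8 h and 307 for 4 h and 8 h.

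The replicate numbers did not pair the arrays: 5 of 18 same-numbered pairs had deviations correlated over 0.1 (range -0.322 to 0.24), and 4 of 12 arrays correlated best with their own number. With the replicate block the counts were 2640, 681 and 9 at 70 min, 4 h and 8 h, and the overlap of 70 min and 8 h was 2. With it the NF-kB list at 8 h was no longer called (adjusted p = 0.0615) and the hypoxia and glycolysis list at 4 h was (0.0435). Dim genes are limited by signal over background, the median of unnamed probes being 4.34.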

Other observations

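The axon guidance, aryl hydrocarbon receptor, YAP and TEAD, histone and ribosomal protein lists were drawn up after the named genes were seen, leaving out members already seen, and each test was set out before its result. Some members left in also belong to lists fixed beforehand. Besides Ccn2, these are Slc7a5 of the aryl hydrocarbon receptor list (ATF4 list) and Robo4 of the axon guidance list (endothelial list).

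Histone genes were among those named at 4 h. Of 21 members not seen before, 4 rose and 1 fell at 70 min and 9 rose at 4 h, where the median log2 fold change was 0.41. Hist1h2bo stood at 1.02 and H2ac25 at 0.81. The hypothesis that histone genes were higher as a group met its test with the preset correlation at 70 min (camera adjusted p = 0.0463, and 0.242 with an estimated correlation) and at 4 h (1.36e-09, and 0.00341 with an estimated correlation). At 8 h the list was not called (adjusted p = 0.0599). From 70 min to 4 h the histone list went higher (adjusted p = 0.00258) and the replication genes lower (0.000944), neither holding with an estimated correlation (0.0623 and 0.129). Histone copies can share probe sequence, so members are not independent.

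Several targets of the transcriptional coactivator YAP and its partner TEAD were among the genes that fell (Ankrd1, Ccn1). Among 15 further targets, of which Ccn2 is also in the immediate early list, the list was lower at 4 h (adjusted p = 0.000438, and 0.0105 with an estimated correlation), with 2 rising and 6 that fell; Nuak2 fell by 0.60 and F3 fell by 0.57. At 70 min it stayed open (adjusted p = 0.866), with 3 rising and 4 falling. Reduced YAP and TEAD activity at 4 h may fit these values and was not measured.

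Cyp1a1, Cyp1b1 and Ahrr rose, but 7 further targets of the aryl hydrocarbon receptor were not called as a list at 70 min (adjusted p = 0.403, median -0.03, 3 rose and 2 fell) or 4 h (adjusted p = 0.201, pointing lower, median -0.18, 2 rose and 1 fell). A general rise of these targets stays open. As a list they were lower at 4 h than at 70 min (adjusted p = 0.00993, but 0.0623 with an estimated correlation), with 2 of 7 falling. That goes against the course of Cyp1a1, which was highest at 4 h, but not every member shared it. Against control, Foxq1 went from 1.03 at 70 min to 0.49 at 4 h and Slc7a5 from 0.38 to -0.18. Aldh3a1 went from 0.49 to 0.78, the same way as Cyp1a1. The hypothesis of lower axon guidance ligands and receptors at 70 min, prompted by the semaphorins and Epha7, stayed open over 54 further members (adjusted p = 0.403), whose median was 0.05. Of these 8 fell, the most Epha3 (-1.27), and 2 rose, Sema7a (0.64) and Unc5b (0.50). Unc50 and Unc5cl, which share a prefix with this family and do not belong to it, were taken out after the result was seen. Ribosomal protein genes were lower at 70 min (adjusted p = 0.0122, but 0.603 with an estimated correlation), by a median of -0.07 over 55 genes of which 1 fell. In comparisons not set out beforehand, camera called them higher at 8 h against control (adjusted p = 0.000181, median 0.05, none passing). They were also higher at 4 h and 8 h than at 70 min (0.000944 and 6.92e-06). None of these held with an estimated correlation (0.434, 0.281 and 0.328).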
